A study of Homo sapiens with 6 samples.

How the data were processed

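RNA sequencing of 6 samples of the breast cancer cell line BT549 was analysed, 3 labelled control and 3 labelled ENL. Per the labels' protocols, total RNA that met limits on amount, purity and integrity was made into mRNA-seq libraries. How mRNA was selected and whether the libraries kept strand are not given in the sources used here. The submitters' processing notes name FastQC, STAR, StringTie, DESeq2 and the genome build hg38, with no versions, roles or parameters, and the annotation behind the gene table is not given in the sources used here.

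The deposited file is 1 table with an estimated count per gene and sample, with a gene symbol per gene. The authors' values are whole numbers, but they behave as an estimated count and not as a count of fragments: low values gathered at multiples of 4 or 1 above them (70.8% to 73.1% of the values from 4 to 43 in the 6 libraries), so that 1 fragment was worth about 4 units. Library totals were 74457932 to 85310759 units. Errors are those of the spread between libraries. Because 1 fragment counts as about 4 units, low values carry a larger counting error than their size shows, and genes with under about 10 units in more than 3 libraries were not tested. Nothing in the table needed rounding.

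Samples were grouped by the treatment label, and columns were matched to samples by name. Replicates were compared before averaging: chi-square per degree of freedom was between 21.15 and 54.72 for the pairs within a group, so no pair agreed within sampling noise and all 6 libraries were counted. Spearman correlations across genes were 0.982 to 0.984 within control, 0.978 to 0.981 within ENL and 0.966 to 0.970 between the groups; genes are not independent replicates.

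Genes were kept with edgeR's filterByExpr (minimum count 10), scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit, robust, and glmQLFTest, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the group alone. Log2 fold changes are ENL against control with their standard errors, and CPM values are normalised with the same factors. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 41 lists, and beside it with an estimated correlation and with fry. Members were also counted with p-values adjusted over the list alone. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

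The design, the gene lists, the rule for named genes and most of the other settings were chosen before the data were examined. By that rule the text names the 10 genes per direction with the largest log2 fold change among those past the threshold, with a mean of at least 5 CPM in the higher group and groups that do not overlap, and the 3 genes per direction with the smallest adjusted p. For each list called by camera it names up to 3 members past the threshold in the list's direction and 1 against it, for each other list up to 2 members past the threshold, and always MLLT1, ESR1, ESR2, GPER1, AHR, VIM, CDH1, EPCAM, MKI67, MYC, PLAU, PLAUR, MMP2, MMP9 and MMP14. Some genes that the rule names are not reported here. Genes with only a clone name and sex-specific genes were left out of naming. In all genes named by the rule that passed the threshold, every library of 1 group lay above every library of the other.

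Symbols were matched to GENCODE 29 (GRCh38, the assembly that hg38 names) for 19806 of 19923 genes (99.4%), which gave the coordinates, counted from 1, and the overlaps of exons. Positions are those of whole genes. Transcript length and GC content were found for 14022 of the 14086 tested genes (99.5%). They are those of the longest annotated transcript of a gene, a protein-coding one where there is any, which need not be the one expressed. Genes that overlap, lie antisense to each other or have near-identical copies are uncertain, since the counting could divide their reads. Overlaps of at least 100 exon bases are pointed out for the genes named by the rule, and shorter overlaps, other genes and near-identical copies only in part.

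The settings chosen in advance were DESeq2's size factors, upper-quartile scaling, library totals alone, the DESeq2 Wald test, limma-voom, no filter on low counts, a filter of at least 10 CPM in 3 libraries, the replicate number as a block, each library left out in turn, edgeR's glmTreat against a 1.2-fold change, and for lists the estimated correlation and fry. Alternatives added after seeing the data were counts divided by 4, genes that share at least 100 exon bases summed, a correction for transcript length and GC content, and the mitochondrially encoded genes left out.

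The procedure was tested on simulated data for this comparison, 10 simulations with 200 changed genes each and 12849 to 12856 genes tested. The test recovered 11.4% of 1.5-fold, 58.6% of 2-fold, 90% of 4-fold and 94.8% of 8-fold changes, and 8.7% of all calls fell on unchanged genes. A list raised 1.5-fold passed camera in 10 of 10 simulations, and 1 of 370 tests of unchanged lists passed. The simulated genes were drawn independently of each other, whereas the estimated correlation in the data was 0.759 for cytosolic ribosomal proteins. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Only 200 genes changed in each simulation, whereas 5404 were called in the data. Benjamini-Hochberg adjustment is stricter when few genes change, so the recovered shares need not hold for this comparison.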

Results

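Gene expression was measured by RNA sequencing in BT549, a human breast cancer cell line, in 3 libraries of cells treated with an agent that the labels call ENL and 3 libraries of control cells. The labels do not spell out ENL and give no dose, duration or vehicle, so the name is used here only as a group name. The comparison asks which genes differed in level between ENL-treated and control cells. The deposited table held estimated counts for 19923 genes, with totals of 80964005, 76387436 and 78578591 in control libraries 1, 2 and 3. ENL libraries 1, 2 and 3 had totals of 74457932, 75493360 and 85310759. Because 1 sequenced fragment was worth about 4 units in this table, the number of fragments was lower than these totals by that factor. A count of 0 in all 6 libraries was found for 2739 genes, and 14086 genes had enough counts to be tested. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

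ENL-treated cells differed from control cells in a large part of the measured transcriptome. More genes rose than fell among cytosolic ribosomal proteins (51 of 54 rose), replication-dependent histones (16 of 29), the ATF4 amino acid response (19 of 34), cholesterol synthesis (14 of 25) and the antioxidant and heat shock responses (14 of 26 and 10 of 19). More fell than rose among genes of DNA replication (21 of 35 fell) and mitosis (18 of 35). These lists were called by limma's camera test with a preset correlation, and each of these calls was lost with an estimated correlation (lowest adjusted p = 0.0783 with an estimated correlation). Among genes with a mean of at least 5 CPM (normalised count scale) in the higher group, the largest rises were those of the cholesterol 25-hydroxylase gene CH25H and the ectonucleotidase gene ENTPD1, whose log2 fold changes were 6.36 ± 0.20 (SE, n = 3 per group) and 5.92 ± 0.15. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2819 genes were higher and 2585 lower in ENL at an adjusted p below 0.05, together 38.4% of the genes tested. A change of at least 2-fold was found for 832 of the higher and 848 of the lower genes. The 3 ENL libraries lay wholly above or wholly below the 3 control libraries for 7606 genes, or 54% of those tested, where chance gives 10%.

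The balance of higher and lower genes depended on how the libraries were scaled. With the trimmed mean scaling used throughout (TMM), 52.2% of the changed genes were higher and the median log2 fold change of all genes was -0.02, whereas scaling by library totals alone gave 1804 higher and 3996 lower genes (31.1% higher) and a median of -0.23. Upper-quartile scaling gave 2356 higher and 3136 lower genes and a median of -0.11. A correction for transcript length and GC content, added after seeing the data, gave 3705 higher and 2560 lower genes (59.1% higher) and a median of 0.04. All changes below are relative to the trimmed mean scale. The composition of the libraries also differed between the groups, since the 87 genes with ribosomal protein symbols took 7.9% ± 0.23 (SD, n = 3) of the counts in control and 12.27% ± 1.32 in ENL, and the mitochondrially encoded genes took 10.24% ± 0.58 and 8.32% ± 0.53. On the first principal component, which held 55.2% of the variance, the control libraries scored from -53.5 to -53.2 and the ENL libraries from 43.4 to 59.5. ENL library 3 stood apart from the other ENL libraries on the component with 14.3% of the variance, with a score of 55.8 against -22 and -26.3. Without ENL library 3, 3156 genes were higher and 2877 lower.

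Among the genes with the largest rises at that level, several encode enzymes, receptors and transcriptional regulators. CH25H (chromosome 10, 89205629 to 89207314, minus strand, GRCh38), which makes 25-hydroxycholesterol, rose from 0.626 ± 0.147 CPM (mean ± SD, n = 3) in control to 51.4 ± 2.5 in ENL (adjusted p = 1.27e-05). ENTPD1 (chromosome 10, 95711779 to 95869695, plus strand), which encodes the cell-surface enzyme CD39, rose from 0.324 ± 0.0292 to 19.7 ± 0.811 CPM (adjusted p = 1.17e-05). NGFR (chromosome 17, 49495293 to 49515017, plus strand), the low-affinity nerve growth factor receptor, rose from 3.02 ± 0.554 to 101 ± 4.84 CPM, a log2 fold change of 5.06 ± 0.16 (adjusted p = 1.27e-05). HEY1 (chromosome 8, 79764010 to 79767863, minus strand), a transcriptional repressor induced by Notch, rose by 4.20 ± 0.20 on the log2 scale, from 6.64 to 122 CPM (adjusted p = 3.48e-05). The histone genes H2AC6 and H2BC21 rose by 4.71 ± 0.16 and 4.30 ± 0.12, the transcription cofactor gene LBH by 3.96 ± 0.42 and the chemokine scavenging receptor gene ACKR3 by 3.91 ± 0.25. ENTPD1 and TUFT1 (2.56 ± 0.07) were among the rises with the smallest adjusted p-value, 1.17e-05. Control libraries were all at 0 for 4 of the genes called higher, LRRC25, HTR1D, KLRD1 and KRT83, and ENL libraries were all at 0 for 24 of the genes called lower. Of these, HTR1D, KLRD1 and KRT83 were chosen after their values were seen.

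The largest falls by the same limit included genes of inflammation, cell shape and signalling. SAA1 (chromosome 11, 18266174 to 18269977, plus strand), an acute-phase protein gene, fell from 12.7 ± 1.01 to 1.10 ± 0.333 CPM, a log2 fold change of -3.54 ± 0.25 (adjusted p = 0.000142). F2RL1 (chromosome 5, 76818933 to 76835315, plus strand), which encodes a protease-activated receptor, fell from 12.8 ± 0.826 to 1.42 ± 0.127 CPM, with a log2 fold change of -3.18 ± 0.15 (adjusted p = 3.1e-05). SHROOM2, a regulator of cell shape, had a log2 fold change of -4.98 ± 0.49, SERPINB3, a protease inhibitor gene, of -3.01 ± 0.36, SIRPB1, a signal regulatory protein gene, of -2.88 ± 0.15, and PITPNB, a phosphatidylinositol transfer protein gene, of -2.86 ± 0.27. PPP1R10, a regulatory subunit of protein phosphatase 1 (-2.56 ± 0.09), SPARC, a matrix glycoprotein gene (-1.83 ± 0.07), and PGK1, a glycolytic enzyme gene (-1.86 ± 0.07), were among the falls with the smallest adjusted p-value, 1.93e-05. PGK1 and SPARC were abundant transcripts, and fell from 879 ± 25.8 to 242 ± 4.55 CPM and from 331 ± 5.20 to 92.7 ± 3.05 CPM.

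Some of the largest changes concerned genes whose exons overlap those of a neighbour, so that the counting could divide the same reads in different ways. HNRNPH2, an RNA-binding protein gene, rose by 4.08 ± 0.23 on the log2 scale, while the readthrough gene RPL36A-HNRNPH2 that shares its exons had a log2 fold change of -4.56 ± 0.58. The sum of both genes rose by 2.26 ± 0.09 (adjusted p = 2.37e-05), and the whole locus with RPL36A, which shares exons with the readthrough gene, had a log2 fold change of 1.02, so no fall of RPL36A-HNRNPH2 can be separated from the assignment of reads. UTP14C had a log2 fold change of -5.09 ± 0.62, and its sum with the overlapping gene ALG11 one of -0.65 ± 0.12 (adjusted p = 0.00662). ARMCX5-GPRASP2, another readthrough gene, had a log2 fold change of 4.39 ± 1.27 (adjusted p = 0.0400), which came to 0.10 (adjusted p = 0.470) for the summed locus. Its call was also lost without a filter on low counts (adjusted p = 0.0734) and without control library 1 (0.102), control library 2 (0.0514), ENL library 1 (0.0932), ENL library 2 (0.0716) or ENL library 3 (0.0875). Exons shared with a neighbour on the same strand also leave ENTPD1, SIRPB1, BUB1B, AHRR, TIGAR and IRF9, described elsewhere, uncertain: summed with that neighbour their log2 fold changes were 5.52, -2.89, -1.07, -0.42, -1.12 and 0.66, and each kept its call. Exons of a gene on the opposite strand overlap those of TAGLN, HSP90AA1, DNAJB1, DNAJB9, SQSTM1, BECN1, SERPINB3, FEN1, SREBF1, SLC16A3, CCND1, DOT1L and PLAU, whose values are uncertain for that reason.

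**Figure D1:**
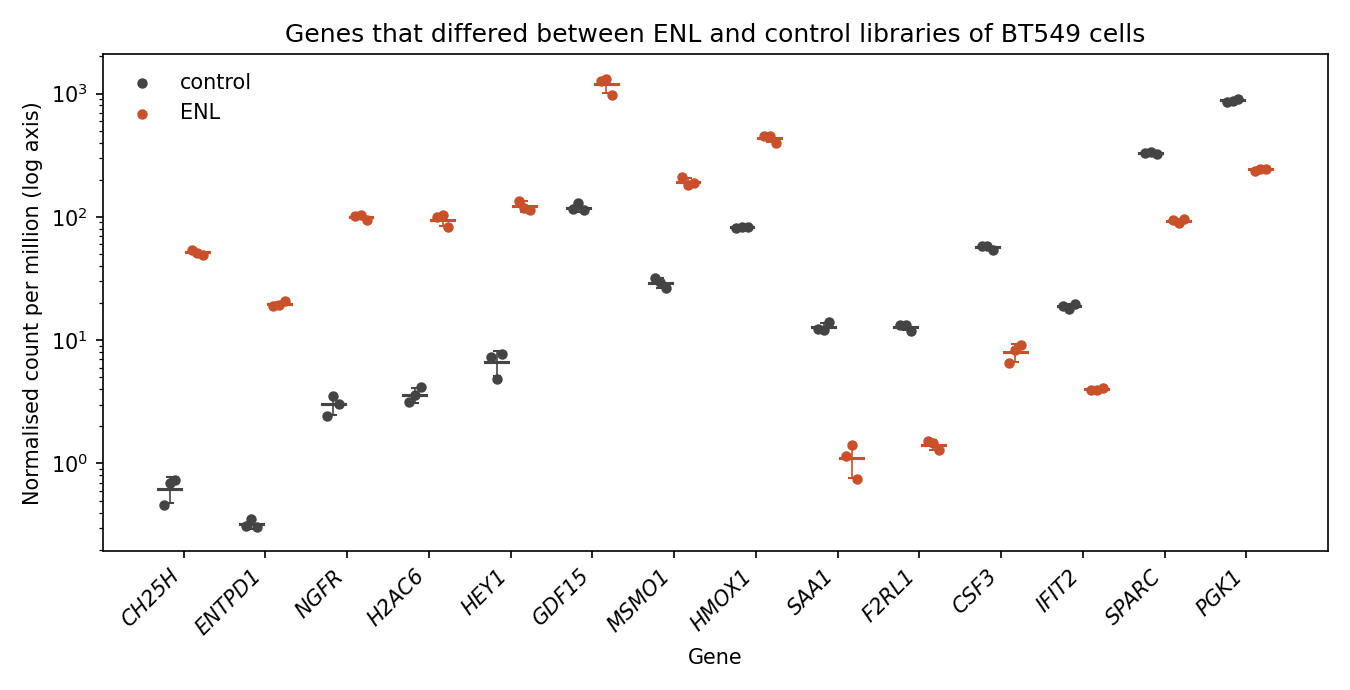
Normalised counts in CPM (log axis) of 14 genes in the 3 control and 3 ENL libraries of BT549 cells; points are libraries, horizontal bars are group means and vertical bars are SDs. The 3 ENL libraries lie on 1 side of the 3 control libraries for each gene, from CH25H (0.626 against 51.4 CPM) to PGK1 (879 against 242 CPM). The genes were taken from those named by the rule, by size of change without overlap or by small p-values. Their separation is therefore no result of its own.

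Gene lists were compared with all other genes in limma's camera test with Benjamini-Hochberg adjustment over 41 lists. It called 19 lists, 13 towards higher and 6 towards lower levels in ENL. Camera assumes a small preset correlation between genes. With an estimated correlation it called 0 lists (lowest adjusted p = 0.0783), although 12 of the 19 had an unadjusted p below 0.05 there. That loss cannot be put down to correlation between genes alone. The estimates for cholesterol synthesis and aryl hydrocarbon receptor targets, -0.03 and -0.093, lay below the preset 0.01. Limma's fry test, which does not compare a list with other genes, called 28. Genes given only in parentheses after a count were chosen after their values were seen, to name the members of small counts.

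Cytosolic ribosomal protein genes, which encode the protein part of the translation machinery, rose almost as a block. Of 54 measured members 51 rose, 0 fell and 3 (RPL8, RPS3A and RPS19) did not pass, or 52 rose and 0 fell when adjusted over the list alone. The median log2 fold change was 0.82 (camera adjusted p = 3.94e-20, adjusted p = 0.333 with an estimated correlation). RPL12 rose by 1.40 ± 0.12 on the log2 scale, from 1042 ± 53.7 to 2742 ± 378 CPM, RPS12 by 1.21 ± 0.13 and RPL10A by 0.96 ± 0.10 (adjusted p = 0.000293, 0.000739 and 0.000536). Ribosomal protein genes have many pseudogenes that could share reads with them, which leaves single members uncertain. The rise moved with the larger ribosomal protein share of the ENL libraries, to which these genes themselves belong, and the median was 0.61 under scaling by library totals.

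Replication-dependent histone genes, whose products package newly made DNA, showed the highest list median of the 19, 1.40 (camera adjusted p = 2.11e-09, adjusted p = 0.0783 with an estimated correlation). Of 29 measured members 16 rose and 0 fell, with the same counts when adjusted over the list alone. H2AC6 rose from 3.61 ± 0.506 to 94.6 ± 10.8 CPM, H2AC18 by 3.44 ± 0.14 on the log2 scale and H2BC5 by 3.28 ± 0.19. Rises were found in every class measured: 7 of 10 H2B genes, 4 of 9 H2A genes, and 2 of 4 H3 genes (H3C4 and H3C10), 2 of 4 H4 genes (H4C9 and H4C12) and 1 of 2 H1 genes (H1-2). The members are near-identical to one another, so reads could be divided between them, and H2AC18 has a nearly identical neighbour.

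In 3 lists of stress-response genes more members rose than fell. In the list of ATF4 targets and the amino acid response, which cells use under amino acid shortage or endoplasmic reticulum stress, 19 of 34 measured members rose and 2 (CHAC1 and PSPH) fell, or 20 and 2 adjusted over the list alone. Their median was 0.54 (camera adjusted p = 1.07e-08, adjusted p = 0.0783 with an estimated correlation). NUPR1, a stress-induced chromatin protein gene, rose from 40.3 ± 3.57 to 296 ± 50.9 CPM, TRIB3, a pseudokinase gene, by 1.75 ± 0.08 on the log2 scale and STC2, a stanniocalcin gene, by 1.74 ± 0.08, whereas the serine synthesis gene PSPH had a log2 fold change of -1.03 ± 0.10. Of the heat shock genes, which encode protein chaperones, 10 of 19 rose and 3 (HSP90AA1, SERPINH1 and DNAJA1) fell, with the same counts adjusted over the list alone. Their median was 0.40 (camera adjusted p = 0.00025, adjusted p = 0.0892 with an estimated correlation). HSPA1A and HSPA1B rose by 2.55 ± 0.11 and 2.58 ± 0.13, although these near-identical copies share reads, DNAJB1 rose by 1.61 ± 0.07, and the abundant HSP90AA1 fell from 4025 ± 102 to 1846 ± 37.2 CPM. Antioxidant genes controlled by NRF2 rose in 14 of 26 cases and fell in 2 (ABCC2 and GCLM), again with the same counts adjusted over the list alone. Their median was 0.33 (camera adjusted p = 3.6e-05, adjusted p = 0.127 with an estimated correlation). HMOX1, the haem-degrading enzyme gene, rose from 82.4 ± 0.796 to 434 ± 31.2 CPM, OSGIN1 by 1.90 ± 0.11 on the log2 scale and the ferritin light chain gene FTL, which has pseudogenes, by 2.05 ± 0.13, while the transporter gene ABCC2 had a log2 fold change of -1.45 ± 0.19.

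Metallothionein genes, which encode metal-binding proteins, had a median of 0.74 over 7 measured members, of which 3 (MT1F, MT1X and MT1E) rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0303, adjusted p = 0.455 with an estimated correlation). MT1F rose by 2.48 ± 0.28, MT1X by 1.05 ± 0.16 and MT1E by 0.74 ± 0.16, but the members are near-identical. The list's call was lost in 6 of 18 other settings (highest adjusted p = 0.131), among them those without control library 3 (0.0553), ENL library 1 (0.0746) or ENL library 2 (0.131).

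Cholesterol synthesis and uptake genes, most of them targets of SREBP2, rose in 14 of 25 cases and fell in 1, with the same counts adjusted over the list alone. The median log2 fold change was 0.84 (camera adjusted p = 2.64e-07, adjusted p = 0.0783 with an estimated correlation). MSMO1, a sterol methyl oxidase gene, rose from 29.2 ± 2.70 to 193 ± 14.4 CPM, the isomerase gene IDI1 by 1.99 ± 0.09 on the log2 scale and the squalene synthase gene FDFT1 by 1.36 ± 0.07 (adjusted p = 1.93e-05, 2.65e-05 and 4.82e-05). Among autophagy and lysosome genes 15 of 32 rose and 3 (BECN1, ATG5 and CTSB) fell, or 16 and 3 adjusted over the list alone. Their median was 0.42 (camera adjusted p = 0.000309, adjusted p = 0.127 with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 697 ± 29.3 to 2251 ± 115 CPM, the sialidase gene NEU1 by 1.21 ± 0.11 on the log2 scale and the lysosomal transcription factor gene TFE3 by 0.91 ± 0.07, and BECN1 had a log2 fold change of -0.51 ± 0.09.

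Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, rose in 7 of 10 cases and fell in 1 (AHRR), with the same counts adjusted over the list alone. Their median was 1.04 (camera adjusted p = 6.71e-05, adjusted p = 0.0834 with an estimated correlation). STC2, the amino acid transporter gene SLC7A5 (1.01 ± 0.07) and the antioxidant regulator gene NFE2L2 (1.07 ± 0.08) led the list by adjusted p. STC2 and SLC7A5 are also in the ATF4 list. LRRC25, at 0 in all control libraries, was higher by at least 1.98 on the log2 scale against a floor of 3 fragments per group, and the median with LRRC25 at that bound was also 1.04. CYP1A1, the classic target of the receptor, had a log2 fold change of -0.40 ± 0.44 (adjusted p = 0.503) at a level of 0.393 CPM in control, while CYP1B1 rose by 1.41 ± 0.14 and TIPARP by 1.32 ± 0.12. These 3 genes were chosen after their values were seen. AHRR, the receptor's repressor, had a log2 fold change of -0.67 ± 0.19 (adjusted p = 0.0290). Its call was lost after correction for transcript length and GC content (adjusted p = 0.0539) and without control library 2 (0.0519), ENL library 1 (0.0818), ENL library 2 (0.0702) or ENL library 3 (0.0581). AHR itself rose by 0.58 ± 0.12 (adjusted p = 0.00995), but not under scaling by library totals, where its log2 fold change was 0.38 (adjusted p = 0.0596).

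TGF-beta response genes rose in 11 of 22 cases and fell in 5 (among them TGFBR2, LTBP1, LTBP2 and SMAD6), or 13 and 5 adjusted over the list alone. Their median was 0.64 (camera adjusted p = 0.000247, adjusted p = 0.0889 with an estimated correlation). The smooth muscle actin gene ACTA2 rose from 36.5 ± 3.37 to 473 ± 35.3 CPM, the smooth muscle marker TAGLN by 2.45 ± 0.12 on the log2 scale and the transcription factor gene BHLHE40 by 2.67 ± 0.08, while the receptor gene TGFBR2 fell from 210 ± 10.9 to 83.1 ± 11 CPM. ACTA2 overlaps FAS on the opposite strand, and no strand setting of the counting is given in the sources used here. Notch pathway genes rose in 6 of 12 cases and fell in 1 (NOTCH3), with the same counts adjusted over the list alone (camera adjusted p = 0.0363, adjusted p = 0.202 with an estimated correlation). Beside HEY1, HES4 rose by 2.63 ± 0.17 and the ligand gene JAG1 by 1.67 ± 0.17, and the receptor gene NOTCH3 had a log2 fold change of -1.05 ± 0.08. The list's median was 0.07 and its mean 0.55, and the median turned to -0.01 under upper-quartile scaling and to -0.13 under library totals. Its call was lost in 6 of 19 other settings (highest adjusted p = 0.259), among them those without control library 1 (0.0696), ENL library 2 (0.0632) or ENL library 3 (0.203).

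Targets of p53, the DNA damage response factor, rose in 11 of 24 cases and fell in 3 (TIGAR, SESN1 and AEN), with the same counts adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.000426, adjusted p = 0.0892 with an estimated correlation). GDF15, a stress-induced cytokine gene, rose from 119 ± 8.76 to 1188 ± 183 CPM, GADD45A by 1.90 ± 0.10 on the log2 scale and SESN2 by 1.2 ± 0.07, and the fructose bisphosphatase gene TIGAR had a log2 fold change of -1.77 ± 0.14. SESN2 is also in the ATF4 list. The classic targets CDKN1A and MDM2, chosen after their values were seen, had log2 fold changes of 0.08 ± 0.09 (adjusted p = 0.473) and 0.58 ± 0.90 (adjusted p = 0.646). Immediate early and AP-1 genes, which respond to growth signals within minutes, rose in 11 of 30 cases and fell in 6, or 12 and 6 adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.0112, adjusted p = 0.127 with an estimated correlation). The nuclear receptor gene NR4A1 rose by 2.32 ± 0.15, the phosphatase gene DUSP4 by 2.26 ± 0.08 and IER3 by 2.25 ± 0.12, while SPRY4, an inhibitor of growth factor signalling, had a log2 fold change of -1.45 ± 0.08. This call was lost in 3 of 19 other settings (highest adjusted p = 0.0739), among them that without ENL library 3 (0.0505).

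More cell cycle genes fell than rose in ENL. In the list of G1/S and DNA replication genes 21 of 35 fell and 2 (CDT1 and MCM5) rose, with the same counts adjusted over the list alone. Their median was -0.47 (camera adjusted p = 2.56e-05, adjusted p = 0.0834 with an estimated correlation). The log2 fold changes were -1.10 ± 0.10 for the transcription factor gene E2F2 and -0.78 ± 0.08 for the flap endonuclease gene FEN1. CDT1, which licenses replication origins, rose by 1.34 ± 0.11. Of the mitosis and G2/M genes 18 of 35 fell and 3 (CDC20, UBE2C and PLK1) rose, or 19 and 3 adjusted over the list alone. Their median was -0.47 (camera adjusted p = 0.00149, adjusted p = 0.286 with an estimated correlation). The mitotic kinase gene AURKA had a log2 fold change of -0.77 ± 0.07, the checkpoint kinase gene BUB1B one of -1.08 ± 0.13 and the kinesin gene KIF4A one of -0.63 ± 0.08, and CDC20, an activator of the anaphase-promoting complex, rose by 0.80 ± 0.09. The proliferation marker MKI67 had a log2 fold change of -0.59 ± 0.31 and did not pass (adjusted p = 0.187).

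Hypoxia and glycolysis genes fell in 12 of 31 cases and rose in 3 (ADM, HK2 and KDM3A), or 12 and 4 adjusted over the list alone. Their median was -0.23 (camera adjusted p = 0.0134, adjusted p = 0.287 with an estimated correlation). Beside PGK1, PGAM1 had a log2 fold change of -0.81 ± 0.08 and the lactate transporter gene SLC16A3 one of -0.86 ± 0.09, and the vasoactive peptide gene ADM rose by 1.92 ± 0.09. The call was lost without ENL library 3 (adjusted p = 0.112), the highest value over 19 other settings. Ribosome biogenesis and MYC target genes fell in 11 of 30 cases and rose in 3 (NPM1, SRM and FBL), with the same counts adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.0473, adjusted p = 0.401 with an estimated correlation). The transferrin receptor gene TFRC fell from 365 ± 20.3 to 131 ± 20.9 CPM, ODC1, an enzyme gene of polyamine synthesis, had a log2 fold change of -0.82 ± 0.07 and LDHA one of -0.93 ± 0.13, while the nucleolar protein gene NPM1 rose by 0.70 ± 0.11. This call was lost in 7 of 19 other settings (highest adjusted p = 0.126), among them those without control library 2 (0.126), control library 3 (0.0553), ENL library 1 (0.0695) or ENL library 3 (0.123).

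Type I interferon response genes fell in 12 of 35 cases and rose in 4 (IFI44L, IRF9, IRF7 and ISG15), or 13 and 5 adjusted over the list alone. Their median was -0.52 (camera adjusted p = 0.0347, adjusted p = 0.161 with an estimated correlation). IFIT2, IFIT1 and IFIT3, neighbouring interferon-induced genes on chromosome 10, had log2 fold changes of -2.23 ± 0.11, -2.14 ± 0.17 and -1.95 ± 0.20, and IFIT2 fell from 18.8 ± 0.924 to 4 ± 0.115 CPM. IRF9, a transcription factor of the same pathway, rose by 1.42 ± 0.17. The list's call was lost in 8 of 19 other settings (highest adjusted p = 0.191), among them those without control library 1 (0.053), control library 2 (0.0642), ENL library 2 (0.0819) or ENL library 3 (0.115). Immune cell markers were measured for 9 of 20 listed genes, of which 3 (CORO1A, CD14 and CSF1R) fell and 0 rose, over all genes and adjusted over the list alone. Their median was -1.41 (camera adjusted p = 0.0309, adjusted p = 0.438 with an estimated correlation). CORO1A fell from 13.5 ± 0.977 to 3.15 ± 0.124 CPM and CD14 from 9.68 ± 1.31 to 1.71 ± 0.565 CPM. CSF1R was near the floor, at 0.421 ± 0.129 CPM in control and 0.0437 ± 0.0384 in ENL (adjusted p = 0.0281). Its call was lost without a filter on low counts (adjusted p = 0.0610) and without control library 1 (0.0642), control library 2 (0.0969), control library 3 (0.0835) or ENL library 2 (0.0716). The list's call was lost in 6 of 17 other settings (highest adjusted p = 0.149), among them those without control library 2 (0.126) or ENL library 3 (0.149).

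**Figure D2:**
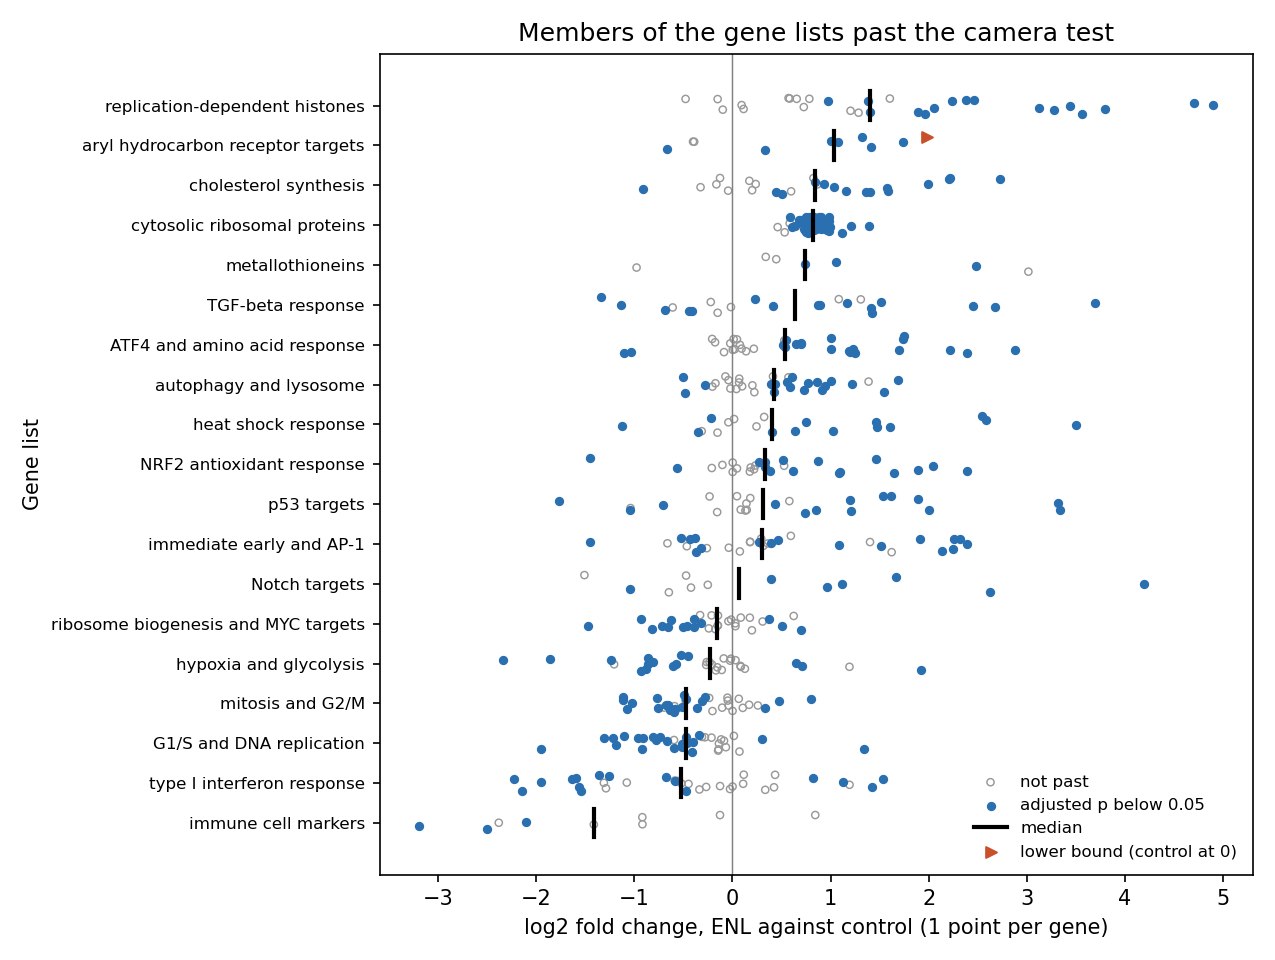
Log2 fold change of ENL against control for each measured member of the 19 gene lists called by camera; filled points passed an adjusted p of 0.05, open points did not, black bars are list medians and the triangle is the lower bound of 1.98 for LRRC25, whose control libraries were at 0. The medians run from -1.41 for immune cell markers to 1.40 for histones, and that of Notch targets, 0.07, turns to -0.13 under scaling by library totals.

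The remaining 22 lists were not called. In the mesenchymal list 9 of 22 genes rose and 4 (among them SPARC, TNC and MSN) fell, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.412). SNAI2, a transcription factor gene of epithelial to mesenchymal transition, rose by 1.87 ± 0.08, and the intermediate filament gene VIM rose from 2744 ± 453 to 5949 ± 503 CPM (adjusted p = 0.00122). Epithelial junction and keratin genes rose in 3 of 18 cases (KRT7, KRT8 and ELF3) and fell in 3 (CLDN7, CLDN4 and KRT5), with the same counts adjusted over the list alone (camera adjusted p = 0.905). KRT8 rose by 1.27 ± 0.15, although KRT18 overlaps it on the opposite strand, and the claudin gene CLDN4 had a log2 fold change of -1.52 ± 0.18. CDH1, the gene of the epithelial adhesion protein E-cadherin, was near the floor in both groups, at 0.205 ± 0.177 and 0.175 ± 0.0266 CPM (adjusted p = 0.870), and EPCAM, another epithelial marker, had too few counts to be tested, at 0, 0 and 11 units in the control libraries and 17, 8 and 0 in the ENL libraries. The log2 fold change of CDH1 turned from -0.23 to 0.66 under limma-voom. It was also positive with the replicate block and without control library 2.

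Of the matrix protease and plasminogen activation genes 10 of 26 fell and 3 (ADAMTS1, TIMP3 and MMP3) rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.205). The urokinase receptor gene PLAUR fell from 169 ± 4.72 to 82.9 ± 14.4 CPM (adjusted p = 0.00132), the membrane-bound protease gene MMP14 had a log2 fold change of -0.55 ± 0.07 (adjusted p = 0.00156) and ADAM12 one of -1.33 ± 0.11, while ADAMTS1 rose by 2.67 ± 0.14. The urokinase gene PLAU had a log2 fold change of -0.35 ± 0.08 (adjusted p = 0.0153), and its call was lost without control library 3 (-0.31, adjusted p = 0.0725). The gelatinase genes MMP2 and MMP9 did not pass, at 0.08 ± 0.21 (adjusted p = 0.797) and -0.24 ± 0.55 (adjusted p = 0.760). Both signs turned in other settings: MMP2 was at -0.13 under library totals and MMP9 at 0.32 without control library 2. Collagen and matrix glycoprotein genes rose in 6 of 27 cases and fell in 8, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.353), with a log2 fold change of -0.93 ± 0.09 for COL5A1. Integrin and focal adhesion genes rose in 7 of 26 cases and fell in 5 (ITGA6, ITGA4, ITGB5, CAV1 and ITGA3), with the same counts adjusted over the list alone (camera adjusted p = 0.845). The adaptor gene BCAR1 rose by 1.75 ± 0.14 and the integrin gene ITGB4 by 0.70 ± 0.08. YAP/TAZ targets rose in 7 of 21 cases and fell in 5 (NT5E, ASAP1, AMOTL2, WWC1 and CRIM1), or 8 and 6 adjusted over the list alone (camera adjusted p = 0.447), with a rise of 1.30 ± 0.07 for the matricellular protein gene CCN1 and of 2.29 ± 0.13 for GADD45B.

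Inflammatory genes controlled by NF-kB rose in 11 of 31 cases and fell in 10, or 13 and 11 adjusted over the list alone (camera adjusted p = 0.619). The granulocyte growth factor gene CSF3 fell from 56.9 ± 2.35 to 8.03 ± 1.34 CPM and the chemokine gene CCL20 from 50.3 ± 1.43 to 8.54 ± 0.600 CPM. Antigen presentation genes rose in 2 of 19 cases (TAP1 and HLA-E) and fell in 3 (ERAP2, NLRC5 and TAPBP), or 2 and 2 adjusted over the list alone (camera adjusted p = 0.765), with rises of 0.77 ± 0.11 for HLA-E and 0.85 ± 0.13 for the peptide transporter gene TAP1. In the list of endoplasmic reticulum chaperones and the unfolded protein response 10 of 25 genes fell and 4 (DNAJB9, HERPUD1, XBP1 and HSPA5) rose, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.546). DNAJB9 rose by 2.12 ± 0.10 and HERPUD1 by 1.80 ± 0.11. Regulators of apoptosis rose in 7 of 31 cases and fell in 8, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.787). The BH3-only gene BBC3 rose by 2.00 ± 0.12, and the death receptor adaptor gene FADD had a log2 fold change of -1.63 ± 0.09. Ferroptosis regulators rose in 7 and fell in 7 of 20 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.33). HMOX1 and FTL were again among those that rose.

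Among metabolic lists, fatty acid synthesis genes rose in 5 of 20 cases (SREBF1, SCD, ME1, ELOVL5 and FASN) and fell in 5 (ELOVL6, HILPDA, GPAM, PLIN2 and ACLY), with the same counts adjusted over the list alone (camera adjusted p = 0.812). The lipogenic transcription factor gene SREBF1 rose by 1.19 ± 0.07, and the lipid droplet gene PLIN2 had a log2 fold change of -0.86 ± 0.07. Fatty acid oxidation and PPAR target genes fell in 9 of 25 cases and rose in 5 (PPARGC1A, UCP2, PDK4, PPARD and PPARG), or 9 and 7 adjusted over the list alone (camera adjusted p = 0.316), and ANGPTL4 fell from 281 ± 14.1 to 79.5 ± 9.51 CPM. Nuclear-encoded oxidative phosphorylation genes rose in 4 of 38 cases (UQCRB, COX5A, COX6A1 and NDUFV1) and fell in 2 (NDUFS1 and ATP5F1A), with the same counts adjusted over the list alone (camera adjusted p = 0.448). COX5A rose by 0.57 ± 0.11, and NDUFS1 had a log2 fold change of -0.52 ± 0.08. Of the 13 mitochondrially encoded genes 4 (MT-ATP8, MT-CYB, MT-ATP6 and MT-CO3) fell and 2 (MT-ND6 and MT-ND5) rose, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.334), and MT-CYB fell from 6908 ± 345 to 3511 ± 382 CPM while MT-ATP8 had a log2 fold change of -0.99 ± 0.11.

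Estrogen receptor targets rose in 6 of 19 cases and fell in 2 (CCND1 and CA12), or 7 and 2 adjusted over the list alone (camera adjusted p = 0.117), with a rise of 1.30 ± 0.08 for the transcription factor gene XBP1 beside that of STC2. The estrogen receptor genes ESR1 and ESR2 were near the floor, with log2 fold changes of -0.19 ± 0.43 (adjusted p = 0.748) and -1.98 ± 1.01 (adjusted p = 0.163), and GPER1, a membrane estrogen receptor gene, had too few counts to be tested, with 4 units in control library 2 and 0 in the others. Without ENL library 2 the log2 fold change of ESR1 turned to 0.08. Wnt targets rose in 2 of 12 cases (BAMBI and NKD2) and fell in 2 (DKK1 and CCND1), with the same counts adjusted over the list alone (camera adjusted p = 0.447). The Wnt antagonist gene DKK1 fell from 68.1 ± 6.74 to 11.3 ± 1.86 CPM, and the cyclin D1 gene CCND1 had a log2 fold change of -1.16 ± 0.07. The list of the super elongation complex, which includes MLLT1, a gene that shares the name ENL, and of HOXA genes rose in 5 of 24 cases (HOXA5, ELL2, HOXA9, DOT1L and CCNT1) and fell in 5 (HOXA11, MEIS1, CTR9, MLLT1 and HEXIM1), with the same counts adjusted over the list alone (camera adjusted p = 0.759). MLLT1 had a log2 fold change of -0.44 ± 0.08 (adjusted p = 0.00609), the elongation factor gene ELL2 rose by 1.44 ± 0.10 and the histone methyltransferase gene DOT1L by 0.74 ± 0.07. MYC did not pass, at 53.8 ± 44.0 CPM in control and 33.9 ± 3 in ENL (adjusted p = 0.386). The control mean rested on control library 3, with 8890 units against 2435 and 2340 in the others, and without that library the log2 fold change of MYC turned from -0.66 to 0.26 (adjusted p = 0.176, within a range of 0.176 to 0.621 over 18 other settings).

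Markers of other cell types gave no further call. Luminal breast markers rose in 2 of 9 cases (XBP1 and KRT8) and fell in 1 (FOXA1) (camera adjusted p = 0.759), and basal keratinocyte markers rose in 2 of 12 cases (S100A2 and LAMA3) and fell in 2 (KRT15 and KRT5) (camera adjusted p = 0.447), with a rise of 0.85 ± 0.15 for the laminin gene LAMA3 and a log2 fold change of -2.49 ± 0.21 for the keratin gene KRT15. Endothelial markers rose in 0 of 5 cases and fell in 1 (ROBO4, -1.65 ± 0.15, camera adjusted p = 0.199), and erythroid and hepatocyte markers rose in 0 and fell in 0 of 9 cases (camera adjusted p = 0.81, edgeR quasi-likelihood test for the genes). The counts of these 4 lists were the same when adjusted over the list alone. Signs of the median, mean and test differed for several lists that were not called: the median was negative and the camera direction upward for the estrogen (-0.09), antigen presentation (-0.04), luminal (-0.13), super elongation (-0.04) and erythroid and hepatocyte (-0.18) lists, the means of antigen presentation and super elongation genes were positive (0.15 and 0.06), the apoptosis list had a median of -0.12 and a mean of 0.02, and the fatty acid oxidation list a median of 0.01 and a mean of -0.17. Under library totals the medians of the mesenchymal, YAP/TAZ, ferroptosis, oxidative phosphorylation and fatty acid oxidation lists turned negative, at -0.07, -0.14, -0.17, -0.11 and -0.21.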

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

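The tests on counts divided by 4, summed genes that share exons, transcript length and GC content, and mitochondrially encoded genes left out were chosen only after the data were seen. The counts of higher, lower and at least 2-fold changed genes and of called lists stayed within 1.5 times their values of 2819, 2585, 1680 and 19, apart from the following. Library totals alone gave 1804 higher and 3996 lower genes, in line with the shift of the median of all genes to -0.227. The filter of at least 10 CPM in 3 libraries gave 857 genes changed at least 2-fold, with 9551 genes tested instead of 14086. Testing against a 1.2-fold change gave 1713 lower genes, as its stricter criterion implies. The estimated correlation gave 0 lists. For cholesterol synthesis and aryl hydrocarbon receptor targets the estimates were -0.03 and -0.093, below the preset 0.01. Their unadjusted camera p still rose, from 2.57e-08 to 0.00344 and from 1.15e-05 to 0.0102. These values argue against a higher correlation between genes as the reason for these lists. The loss of calls with the estimated correlation therefore does not measure correlation between genes alone, and its cause was not tested further. With each library left out in turn there were 2072 to 3156 higher, 1743 to 2877 lower and 1440 to 1876 at least 2-fold changed genes and 14 to 17 lists. No gene called in the main comparison was called in the other direction in any setting except with genes that share exons summed, where 4 were. There each summed locus was compared only with the first of its genes by name, so reversals of its other genes are not in that count. One of those other genes is RPL36A-HNRNPH2, whose log2 fold change became 1.02, that of the locus it forms with HNRNPH2 and RPL36A. Apart from RPL36A-HNRNPH2 no named gene past the threshold reversed, and 12 of the 19 lists passed in every setting other than the estimated correlation. At the depth and number of libraries used here, 11.4% of simulated 1.5-fold and 58.6% of 2-fold changes were recovered, and other depths were not simulated. These shares are for 200 changed genes per simulation and need not hold for the data, where 5404 genes were called.

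With the replicate number as a block there were 2631 higher, 2310 lower and 1507 at least 2-fold changed genes and 15 lists, and the block ended the calls of CSF1R (adjusted p = 0.0528) among named genes and of 4 lists, those of type I interferon, ribosome biogenesis, Notch and immune cell markers. Deviations of samples with the same number correlated at 0.03, 0.046 and 0.08. Those of samples with different numbers ran from -0.075 to 0.032, and only that of ENL library 1 with control library 2 (0.032) was positive. ENL libraries 2 and 3 each correlated best with the control library of the same number. These small correlations do not settle whether the numbers mark pairs. The block was left out of the main model in advance because the labels do not call the numbers pairs.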

Other observations

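The tests of S phase and of the summed locus of HNRNPH2, and the gene families below, were chosen only after the results were seen. A search of 180 families of genes with a shared name stem and at least 10 tested members found 4 past camera, those with the stems RPL, RPS, HSPA and IRF, and 0 with an estimated correlation (adjusted p = 0.991 for each). The 10 genes with the stem IRF are interferon regulatory factor genes together with the binding protein genes IRF2BP1, IRF2BP2 and IRF2BPL, which are not such factors. Of these 10, 6 rose and 1 (IRF2BP1) fell, with a median log2 fold change of 0.86 (camera adjusted p = 0.00961). IRF1, an interferon regulatory factor gene, rose by 2.44 ± 0.10, from 26.6 to 144 CPM. Of 14 HSPA genes 8 rose and 3 fell, with a median of 0.51 (camera adjusted p = 0.00855), and the stress-inducible HSPA6 rose by 3.04 ± 0.15, from 2.34 to 19.2 CPM.

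Of 54 cytosolic ribosomal protein genes 51 rose and 0 fell, with a median log2 fold change of 0.82 (camera adjusted p = 3.94e-20, adjusted p = 0.333 with an estimated correlation). A bias of the ENL libraries by annotated transcript length was argued against as the whole of this rise. Medians of 1000 sets of genes matched on that length had a central 95% range of -0.086 to 0.29. Oxidative phosphorylation genes, also short by annotation, had a median of 0.104. Length was that of the longest annotated transcript of each gene, so a bias towards shorter expressed transcripts was not tested. A smaller shift by length was not excluded. The correction for transcript length and GC content gave 3705 higher and 2560 lower genes, against 2819 and 2585 without it. The list median stayed above 0 under each of 4 scalings, with a lowest value of 0.61. These scalings moved the median of all genes only from -0.02 to -0.23, too little to bring the list to 0. They therefore cannot exclude scaling as a cause. A candidate explanation is a shared rise of mRNAs that carry a 5' terminal oligopyrimidine tract, the class to which ribosomal protein mRNAs belong: of 19 other mRNAs of that class 15 rose and 0 fell, with a median of 0.7 against a central range of -0.236 to 0.491 in sets matched on mean expression. This goes with the hypothesis but leaves open whether synthesis or stability of these mRNAs changed, and reads shared with pseudogenes were not tested.

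Of 29 histone genes 16 rose and 0 fell, while of 35 G1/S and DNA replication genes 21 fell and 2 rose (adjusted p = 0.0783 and 0.0834 with an estimated correlation in camera). Annotated transcript length was argued against as the whole of this rise. The 26 histone genes with a known length had a median of 1.5 against a range of -0.199 to 0.403 in length-matched sets. That length is of the longest annotated transcript, so a bias towards shorter expressed transcripts was not tested. The lowest list median over the scalings was 1.19. The scalings moved all genes too little to bring it to 0, so they cannot exclude scaling as a cause. More cells in S phase would raise both groups, but the median of G1/S and DNA replication genes was -0.47. Histone mRNAs mostly lack a poly(A) tail, so a difference in mRNA selection between the groups, or more polyadenylated histone transcripts in ENL, stays open and was not tested.

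The split between higher and lower genes moved with the scaling, with a median of -0.23 under library totals. Leaving out the ribosomal protein genes gave -0.16, so they alone did not account for the whole shift. The mitochondrially encoded genes had a lower share of the counts in ENL (8.32% ± 0.53 against 10.24% ± 0.58, SD), so they took no counts from other genes there, and the median of -0.26 without these 13 genes adds nothing to that. Whether the total RNA per cell differed was not measured here.

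Genes that share exons were changed at least 2-fold in opposite directions in 4 of 679 pairs, within the range of 0 to 7 in random pairings of the same genes. The summed counts of HNRNPH2 and RPL36A-HNRNPH2 rose by 2.26 ± 0.09 on the log2 scale (adjusted p = 2.37e-05).

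The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most calls for each count: 2819 higher genes against at most 1 in another split, 2585 lower against at most 2, 1680 changed at least 2-fold against at most 2, and 19 lists against at most 9. Each other split mixed control and ENL libraries in both groups, which widens the spread within groups, so few gene calls could arise there. The split with 9 lists, which put control libraries 1 and 3 with ENL library 3, had 0 higher and 0 lower genes.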
